A study of Mus musculus with 6 samples.

How the data were processed

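Gene expression was measured on Affymetrix perfect-match arrays of the mouse genome in pro-B cells, the early B cell precursors of bone marrow, sorted by flow cytometry as B220+CD43+IgM- cells. There were 3 arrays of wild-type cells and 3 arrays of cells labelled HDAC7 deficient, described as biological triplicates. RNA was amplified by whole transcriptome amplification before biotin labelling and hybridisation, per the labels' protocols. The authors deposited 1 log2 expression value per probe set and array. The normalization method and its software are not given in the sources used here, and the log2 scale was read from the range of the values. Every column of the table was assigned to its sample.

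The table held 45141 probe sets, of which 104 were controls and were set aside, leaving 45037. A platform annotation table gave 1 gene symbol for 28898 of these, several symbols for 551 and no symbol for 15588. Of the probe sets with 1 symbol, 28689 were matched by Entrez gene number to current mouse symbols in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 209 kept the older symbol. Each of the 17097 genes was represented by its probe set with the highest mean over the 6 arrays. For the 7180 genes with more than 1 probe set this choice can matter, and the mean over probe sets was tried as an alternative. Affymetrix probe sets of 1 gene can disagree, and those of Hspa1b did.

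Groups were compared with limma 3.58.1 in R 4.3.3, with group means, moderated variances that follow an intensity trend, two-sided tests and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. No filter on dim probe sets was applied. Changes are log2 values of HDAC7 deficient minus wild type, given ± standard error, and group levels are means ± SD. All adjusted p-values in the text are from limma or from its gene list tests. The number of arrays limits the precision, and an exact permutation test of 3 arrays against 3 cannot give a p below 0.1.

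The test, 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold 474 genes, 413 of them measured here under a single symbol; Igll1, Il7r and Siglech were among the genes without a named probe set here. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists. They were also tested by camera with an estimated correlation and by fry, which asks whether the genes of a list move, on balance, in 1 direction. No list passed fry (lowest adjusted p = 0.283) or camera with an estimated correlation, with all arrays (lowest 0.544), without wild-type replicate 3 (lowest 0.715), with the Xist division described below as a block (lowest 0.453) or with both (lowest 0.943). The naming rule took Hdac7, then for each direction the 14 genes with the largest changes past the threshold, with places left open filled by the smallest unadjusted p. It further took up to 4 members per list by smallest p, or up to 8 for a list that passed camera, and named no clone symbols. Genes named for their values outside this rule are identified as chosen after these values were seen.

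Expression-matched random lists (10000 draws per list) were added after the list results were seen. Arrays were also divided by their Xist level, which the labels do not give; the same division was seen in the hybridisation spike-in controls. A fit with this division as a block, and the same fit without wild-type replicate 3, were added after the data were seen. The other alternatives were leaving out each array, the replicate number as a block, quantile normalization or median centring of the deposited values, leaving out the dimmest 25% or 50% of genes, other variance models, array weights, other probe set choices and other thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

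The fit was tested on simulated data for the same 17097 genes with independent noise of the measured size. With all 6 arrays it recovered 16.4% of genes changed 2-fold, 65.7% of those changed 4-fold and 92.4% of those changed 8-fold, with 126 calls, 10 of them on unchanged genes. Without wild-type replicate 3 the shares were 62.7%, 100% and 100%, with 193 calls, 18 of them on unchanged genes. Noise shared between genes, which real arrays have, was not simulated. Each gene had noise of the same size on every array, so the poorer quality of wild-type replicate 3, described below, was not simulated either.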

Results

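Expression was compared between 3 arrays of sorted wild-type pro-B cells and 3 arrays of sorted pro-B cells labelled HDAC7 deficient. HDAC7 is a class IIa histone deacetylase, and the study asked whether it keeps genes of other lineages silent in B cell precursors. Each array gave 45037 log2 values after controls were set aside, with array medians between 5.83 and 6.15.

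Wild-type replicate 3 stood apart from the other arrays. Across probe sets its correlations with the other 5 arrays ran from 0.70 to 0.82, and its interquartile range was 1.72 against 2.27 to 2.93 elsewhere. Its Actb signal was 1.69 higher at the 3' end than in the middle of the transcript, against 0.16 to 0.26 on the other arrays. Principal component 1, with 83.3% of the variance, placed this array at 139 and the other 5 between -48.4 and 7.35. Xist, the RNA that coats the inactive X chromosome of female cells, divided the arrays across genotypes. It was 8.51, 11.40 and 11.27 on wild-type replicate 3 and HDAC7-deficient replicates 2 and 3 (Xist-high), and 5.38, 5.17 and 4.87 on wild-type replicates 1 and 2 and HDAC7-deficient replicate 1 (Xist-low). Hybridisation spike-in controls divided the arrays in the same way, with means of 9.77 to 10.60 on the Xist-high arrays and 8.43 to 8.93 on the Xist-low arrays. The Y-linked genes Eif2s3y and Kdm5d ran the other way, with 7.77, 8.31 and 9.49 (Eif2s3y) and 7.87, 8.60 and 9.14 (Kdm5d) on the Xist-low arrays and 4.08, 4.41 and 4.72, and 5.58, 5.03 and 5.09, on the Xist-high arrays. The labels do not give the sexes, but the division is thus that of male and female cells, it coincides with that of the spike-ins, and effects of sex and of hybridisation cannot be told apart here.

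**Figure D1:**
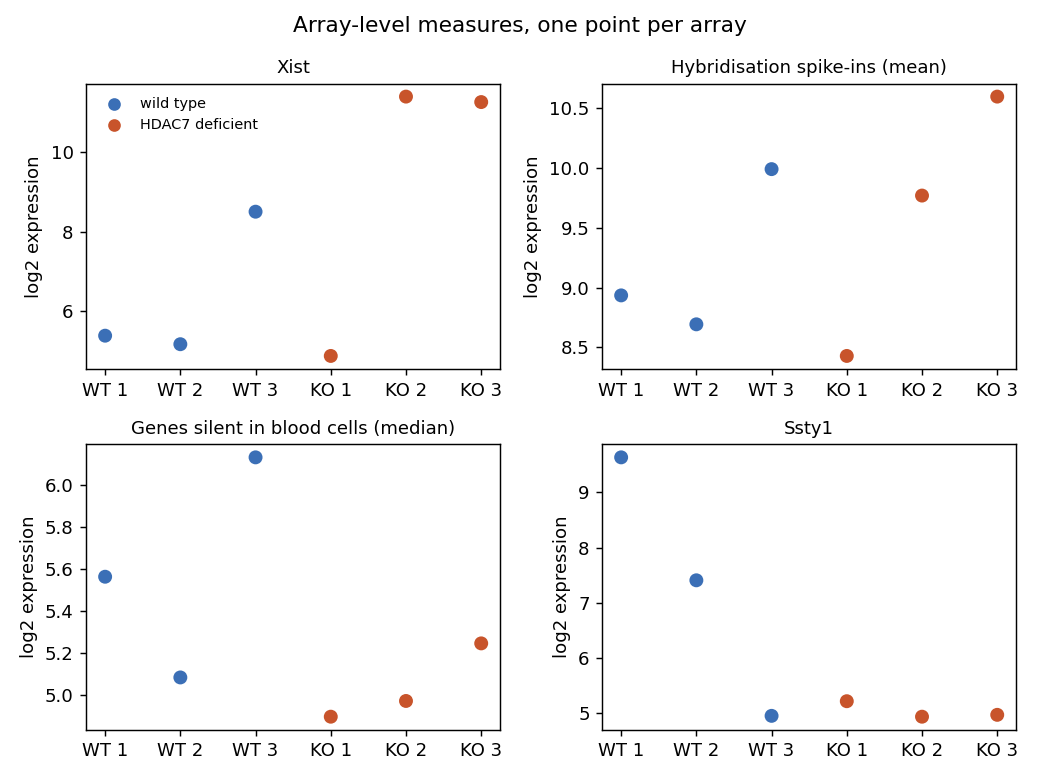
Log2 expression on each of the 6 arrays (WT, wild type; KO, HDAC7 deficient; number, replicate) of Xist, the mean of the hybridisation spike-ins, the median of 157 genes picked by symbol as silent in blood cells, and Ssty1, with 1 point per array. Xist was between 8.51 and 11.40 on WT 3, KO 2 and KO 3 and between 4.87 and 5.38 on the others, and Ssty1 was highest on WT 1 at 9.64.

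Hdac7 itself was not lower on the arrays labelled HDAC7 deficient. Its brighter probe set (1420813_PM_at) gave 8.62 ± 1.15 in wild type and 9.59 ± 0.34 in HDAC7 deficient (SD, n = 3 each), a change of 0.97 ± 0.59 with a limma adjusted p of 0.399. The other probe set (1420812_PM_at) differed by 0.88 ± 0.50, with a limma adjusted p of 0.376 over probe sets. The changes were 0.31 and 0.36 with wild-type replicate 3 left out. Which exons were deleted, and whether these probes lie in them, is not known here, so Hdac7 does not check the labels, and every direction below is that of the arrays labelled HDAC7 deficient.

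The genes with the smallest p-values on the higher side included stress and immediate early genes. Jun, a subunit of the AP-1 transcription factor, was 10.59 ± 0.53 against 7.82 ± 0.20 in wild type, a change of 2.76 ± 0.36. Its partner Fosb differed by 4.16 ± 0.68, Junb by 1.98 ± 0.39, and the inducible heat shock gene Hspa1b by 3.72 ± 0.49. The other Hspa1b probe sets differed by 0.14 and 0.26 at means below 5. The autophagy gene Rb1cc1 differed by 1.41 ± 0.17, the splicing regulator Tra2b by 1.90 ± 0.30, Slfn4 by 2.15 ± 0.38, the guanylate-binding protein gene Gbp8 by 1.56 ± 0.28 and the inflammasome sensor gene Naip5 by 1.35 ± 0.24. Ints6l, Brip1os, Phlda1, Fbxo33 and Srp54b completed the 14, with changes of 1.12 to 1.82. On the lower side, Tpm2, a muscle tropomyosin, differed by -2.12 ± 0.29, the glutathione transferase Gstm6 by -2.06 ± 0.33, the astrocyte filament gene Gfap by -1.76 ± 0.23 and the neuronal calcium sensor gene Hpca by -1.30 ± 0.17. Hpd, Ppp1r32, Efhd1, the olfactory receptor Olfr70, Serpina1b, the endothelial receptor Robo4, Kcng4, Sema3g, Pla2g2f and Col26a1 differed by -0.87 to -1.62. In all 28 genes the 3 arrays of 1 group lay on the same side of the 3 of the other, yet none passed, with limma adjusted p-values of 0.326 to 0.377.

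No gene of 17097 and no probe set of 45037 passed an adjusted p of 0.05 in limma, the smallest being 0.326 and 0.273. At an unadjusted p under 0.05 there were 2165 genes, 602 higher and 1563 lower, and 6340 probe sets, 2689 higher and 3651 lower. The Xist division as a block gave 7288 genes at that level, 2678 higher and 4610 lower, and again none passed. In that fit wild-type replicate 3 is the only wild-type array among the Xist-high ones. The 4275 genes of highest mean expression had a median change of 1.44 within the Xist-high arrays and 0.14 within the Xist-low arrays. The larger count therefore cannot be told apart from the poor quality of that array. Groups did not overlap for 1616 genes higher and 2880 lower on the arrays labelled HDAC7 deficient, 26.3% of genes in all. Chance gives 10% on average over splits of the arrays, but genes vary together, so a single split can lie far from that average. Overlap was not counted for other splits, so an excess over chance was not tested. Leaving out wild-type replicate 3, no gene passed either, with a smallest adjusted p of 0.0645 and 2399 genes at an unadjusted p under 0.05, 887 higher and 1512 lower. The probe sets at that level were then 3547 higher and 3305 lower, so that genes still leaned lower and probe sets did not. With the Xist division as a block and that array left out, 4 genes passed, all higher: Fosb by 3.26 and Fos by 2.53 (limma adjusted p = 1.18e-04 each), Jun by 2.09 (0.00489) and the linker histone gene H1f2 by 1.45 (0.0138). Fos and H1f2 were named after their values were seen, and these changes rest on HDAC7-deficient replicate 1 alone against wild-type replicates 1 and 2.

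The list of immediate early and stress genes, which cells switch on within minutes of a stimulus, had the largest median change of the 22 lists with all 6 arrays. Of its 25 measured members 23 were higher on the arrays labelled HDAC7 deficient, with a median of 1.46, and 13 rose when adjusted over the list alone, against 0 over all genes. Besides Jun, Hspa1b, Fosb and Junb these included Egr1, a zinc finger transcription factor, with 3.25 ± 0.67, the phosphatase gene Dusp2 with 1.46 ± 0.38, Ier2 with 1.24 ± 0.28 and the activation marker Cd69 with 2.94 ± 0.90. The list passed camera upward with an adjusted p of 7.13e-13, but not fry (adjusted p = 0.283), and its adjusted p = 0.544 with an estimated correlation. Its median without wild-type replicate 3 was 1.61, 18 members passed adjusted over the list alone and camera gave 2.93e-23. The median was 0.66 within the Xist-low arrays and 2.17 within the Xist-high arrays. With the Xist division as a block camera gave 1.39e-07, and adjusted p = 0.453 with an estimated correlation.

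**Figure D2:**
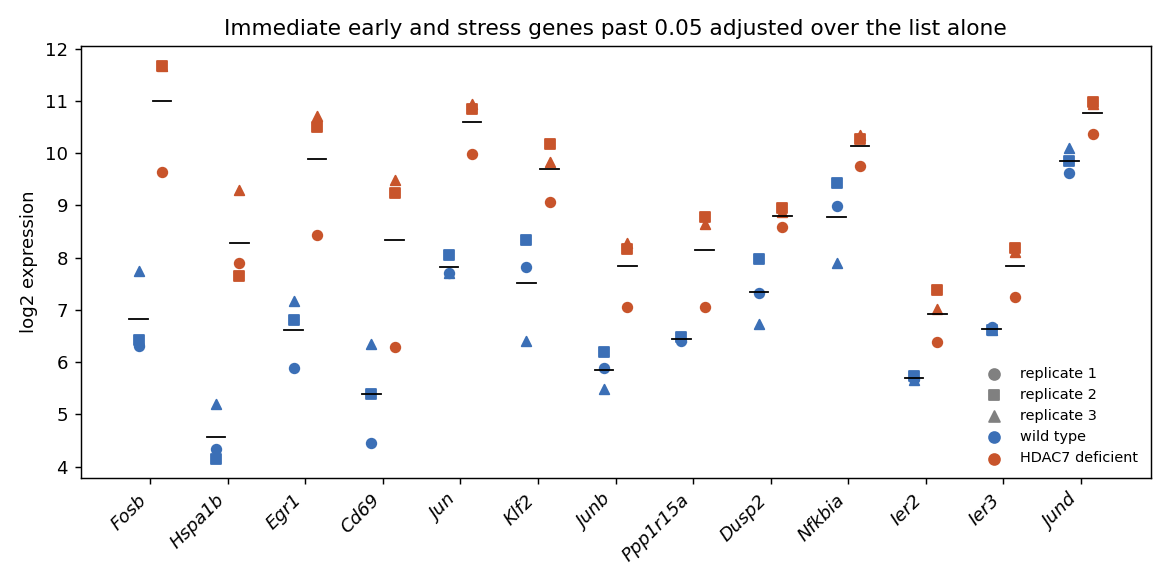
Log2 expression of the 13 immediate early and stress genes past 0.05 adjusted over the list alone, with 1 point per array, shapes for replicates, blue for wild type, orange for HDAC7 deficient and black bars for group means. Cd69 is the 1 gene shown whose groups overlap, with 6.34 on wild-type replicate 3 against 6.29 on HDAC7-deficient replicate 1.

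Several lists of innate immune cells lay higher on the arrays labelled HDAC7 deficient. All 20 measured genes of plasmacytoid dendritic cells were higher, with a median of 1.13, led by the RNA sensor Tlr7 with 1.49 ± 0.48, Klk1 with 2.06 ± 0.73 and Mctp2 with 0.83 ± 0.31. Of 27 macrophage genes 22 were higher (median 0.70), among them the chemokines Ccl3 with 1.27 ± 0.30 and Ccl4 with 1.22 ± 0.29, the fungal receptor Clec7a with 1.35 ± 0.35 and the integrin Itgam with 1.51 ± 0.42. Of 19 neutrophil genes 17 were higher (median 0.73), with the protease genes Mmp8 at 1.45 ± 0.41 and Mmp9 at 1.74 ± 0.83, and of 22 genes of natural killer and other innate lymphoid cells 18 were higher (median 0.73), with Xcl1 at 0.90 ± 0.42 and Prf1, which encodes perforin, at 0.71 ± 0.41. Camera gave adjusted p-values of 2.47e-06, 2.25e-04, 2.91e-04 and 0.00157 for these 4 lists, each with an adjusted p = 0.544 with an estimated correlation. No member passed adjusted over the list alone or over all genes. The lists lay at percentiles 100, 99.92, 96.88 and 99.73 of random lists of matched expression, and at 99.23 or above without wild-type replicate 3. Random lists do not keep the correlation between the genes of a list. Without wild-type replicate 3 Klk1 had a change of 1.35, Mmp9 of 0.72, Xcl1 of 0.58 and Prf1 of 0.32, while Tlr7, Mctp2, Ccl3, Ccl4, Clec7a, Itgam and Mmp8 had 1.47, 0.82, 1.17, 1.16, 1.28, 1.31 and 1.32. The medians without that array were 0.40, 0.22, 0.40 and 0.22, and Ccl3 and Ccl4 then passed adjusted over the list alone among macrophage genes (0.0270 and 0.0368) and Mmp9 among neutrophil genes (0.0433). Within the Xist-low arrays they were 0.13, 0.05, -0.04 and 0.13, against 1.43 to 2.60 within the Xist-high arrays, where that wild-type array is the only one. With the Xist division as a block all 4 passed (adjusted p from 3.81e-05 to 0.00216, and adjusted p = 0.453 with an estimated correlation). With both the block and that array left out none of the 4 passed, with adjusted p-values of 0.128 to 0.839.

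Genes of other lineages did not pass. T cell genes had a median of 0.31 (adjusted p = 0.169), with the costimulatory receptor Cd28 at 0.77 ± 0.29 and Cd6 at -0.71 ± 0.24. Conventional dendritic cell and MHC class II genes had a median of 0.52 (0.169), with the integrin Itgax at 1.55 ± 0.73 and the chemokines Ccl22 and Ccl17 at -0.72 ± 0.19 and -0.69 ± 0.23. Basophil, mast cell and eosinophil genes had a median of 0.11 (0.253), and Ccl3 and Ccl4, which macrophages also make, rose when adjusted over the list alone. Erythroid and megakaryocyte genes had a median of 0.12 (0.322), and without wild-type replicate 3 they passed upward at 0.0413 (adjusted p = 0.725 with an estimated correlation), with Car2, a carbonic anhydrase, at 0.76. Plasma cell genes had a median of 0.92 (0.322), with the joining chain gene Jchain at 1.49 ± 0.58 and the receptor Tnfrsf17 at -0.86 ± 0.25. Stem and progenitor genes had a median of -0.17 (0.531), with Hlf at -1.12 ± 0.43, and stromal and endothelial genes a median of -0.41 (0.163), with the matrix gene Sparc at -0.97 ± 0.42. With wild-type replicate 3 left out the medians were 0.03 for T cell genes, 0.26 for conventional dendritic cell genes (Itgax 0.69), 0.14 for plasma cell genes (Jchain 0.89) and -0.17 for stromal genes (Sparc -0.67). The camera direction turned downward for basophil, mast cell and eosinophil genes (median -0.23, adjusted p = 0.987) and upward for stem and progenitor genes (median -0.01, 0.842, Hlf -0.69). No member of these lists other than Ccl3 and Ccl4 passed adjusted over its list alone. Cd69 passed in the immediate early list (0.0318) and not among T cell genes (0.267). Plasma cell genes lay at percentile 99.99 of random lists of matched expression with all arrays, and at 93.51 without wild-type replicate 3. Without that array conventional dendritic cell genes lay at 99.88, erythroid genes at 99.93 and basophil, mast cell and eosinophil genes at 0. T cell, stem and stromal genes then lay at 71.35, 64.15 and 26.84.

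Early B lineage genes lay slightly higher. Of 26 measured members 20 were higher, with a median of 0.35, the commitment factor Pax5 at 0.82 ± 0.57, Tcf3, which encodes E2A, at 0.73 ± 0.49 and the adaptor Blnk at 0.66 ± 0.47. Camera gave an adjusted p of 0.0319, and adjusted p = 0.714 with an estimated correlation. No member passed adjusted over the list alone. Without wild-type replicate 3 the changes of Pax5, Tcf3 and Blnk were 0.24, 0.20 and 0.19, the median was -0.03 and the direction turned downward (adjusted p = 0.920). Without HDAC7-deficient replicate 1 the call was lost (0.488). With the Xist block the list passed upward (median 0.82, adjusted p = 4.69e-04, and adjusted p = 0.453 with an estimated correlation), as it did with the block and without wild-type replicate 3 (median 0.28, 3.43e-05, and adjusted p = 0.943 with an estimated correlation). The list lay at percentile 10.9 of random lists of matched expression with all arrays, and at 73.3 with the Xist block. Genes of V(D)J recombination and the pre-B cell receptor had a median of 0.23 (adjusted p = 0.135), with the kinase Syk at 1.79 ± 1.23; leaving out wild-type replicate 3 gave Syk 0.21 and a list median of -0.18, downward (0.682). Late B genes had a median of 0.24 (0.135), or 0.11 without that array, with Cd180 at 0.78 ± 0.41, or 0.40. Cell cycle genes had a median of 0.34 (0.0781), and without wild-type replicate 3 a median of -0.19 in the downward direction (0.0429, and adjusted p = 0.875 with an estimated correlation). Centring on array medians kept these directions, and repeated quantile normalization turned the cell cycle list downward. With the Xist block cell cycle and V(D)J genes passed camera upward (medians 0.71 and 0.44, adjusted p = 0.00125 and 0.00279). Both had adjusted p = 0.453 with an estimated correlation, and lay at percentiles 40.4 and 23.9 of random lists of matched expression. With all arrays and no block these percentiles were 6.24 and 11.66. Without wild-type replicate 3 and with no block they were 0 and 0.07, the low end of the matched lists. The replicate number as a block gave cell cycle genes an upward camera adjusted p of 0.0411.

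Genes of cell death, signalling and defence also lay higher. Of 23 cell death and p53 target genes 18 were higher (median 0.64), with Gadd45a, a DNA damage response gene, at 1.72 ± 0.45 and Pmaip1, which encodes the death factor NOXA, at 1.94 ± 0.51. Of 29 cytokine, chemokine and adhesion genes 26 were higher (median 0.73), with Ifng, which encodes interferon gamma, at 1.55 ± 0.51. Of 25 interferon-stimulated genes 23 were higher (median 0.71), with Ifit2 at 1.16 ± 0.33, and of 19 interleukin 7 and STAT5 genes 16 were higher (median 0.75), with the cytokine signalling inhibitor Socs2 at 1.40 ± 0.49. Of 22 genes of histone deacetylases, corepressors and MEF2 factors 19 were higher (median 0.53), with the DNA demethylation enzyme Tet2 at 0.82 ± 0.34 and Hdac10 at 0.61 ± 0.27. Camera gave adjusted p-values of 6.00e-04, 3.12e-05, 1.83e-05, 0.00347 and 0.00172 in that order, each with an adjusted p = 0.544 with an estimated correlation, and no member passed adjusted over the list alone. Leaving out wild-type replicate 3 gave medians of 0.17, 0.26, 0.44, 0.12 and 0.06, the deacetylase list no longer passed (0.0678, with Hdac10 at 0.39), and Gadd45a, Pmaip1 and Mcl1 passed adjusted over the cell death list alone (0.0331, 0.0392 and 0.0331). In the cytokine, chemokine and adhesion list 2 members passed adjusted over that list alone without wild-type replicate 3. These were Ccl3 and Ccl4, which are also in the macrophage list and are not separate support. That array read strongly expressed genes lower: in the 4275 genes of highest mean expression it lay below wild-type replicate 1 by a median difference of -1.22, and these genes had a median change of 0.56 between the groups, or 0.06 without it. The deacetylase list lay at percentile 77.9 and the cell death list at 93.4 of random lists of matched expression, and the other 3 at 99.2 or above, but the interleukin 7 list lay at 84.5 without wild-type replicate 3 and the interferon list at 77.0 with the Xist block. Within the Xist-low arrays the cytokine, interferon and interleukin 7 medians were 0.10, 0.04 and 0.10, and with the block and without wild-type replicate 3 these lists did not pass (0.0660, 0.839 and 0.298). The cell death and deacetylase lists passed upward in that fit (0.00361 and 0.0269, each with adjusted p = 0.943 with an estimated correlation), with medians of 0.24 and 0.14. The 4 sex-linked genes measured did not pass (adjusted p = 0.806), with a median of -0.39, a mean of 0.28 and an upward camera direction.

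**Figure D3:**
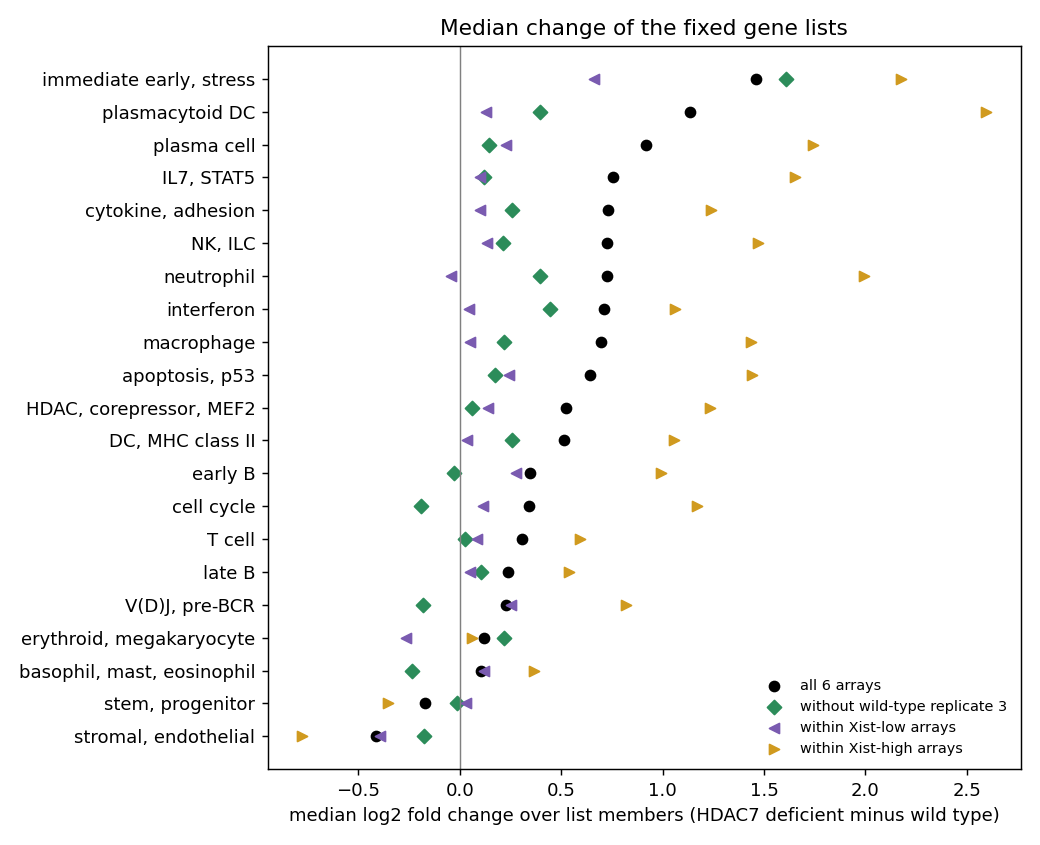
Median log2 change, HDAC7 deficient minus wild type, over the measured members of 21 gene lists (the sex-linked list is left out) with all 6 arrays, without wild-type replicate 3, and within the Xist-low and the Xist-high arrays. The immediate early and stress list lies at 1.46, 1.61, 0.66 and 2.17 in these settings, while the plasmacytoid dendritic cell list lies at 1.13, 0.40, 0.13 and 2.60.

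Genes lower on the arrays labelled HDAC7 deficient were mostly weakly expressed. Of the 1563 lower genes at an unadjusted p under 0.05, 1327 (84.9%) lay below the median gene in mean expression, against 147 of the 602 higher genes (24.4%). Wild-type replicate 3 read dim genes higher: in the 4274 genes of lowest mean expression and the next 4274 it lay above wild-type replicate 1 by medians of 0.43 and 0.44, and the median changes between the groups, -0.30 and -0.38, were -0.11 and -0.18 without it. A set of 157 genes was picked by the first letters of their symbols, after the data were seen. It was meant to hold families silent in blood cells, such as vomeronasal receptors and keratin-associated proteins. First letters alone can also take in expressed genes, such as arginine methyltransferases (Prmt) along with protamines (Prm). The set had medians of 5.56, 5.08 and 6.13 on wild-type replicates 1 to 3 and of 4.90, 4.97 and 5.25 on HDAC7-deficient replicates 1 to 3. In 27 of the 157 genes (17.2%) all arrays labelled HDAC7 deficient lay below all wild-type arrays, against 16.8% of all genes. Chance gives 5% on average over splits of the arrays, and other splits were not counted. The B2 repeat probe sets followed, with 8.71, 8.01 and 9.43 against 7.69, 7.69 and 7.95. The antigenomic controls, which match no mouse sequence, had medians of 3.75, 3.89 and 3.70 against 3.90, 3.99 and 3.98.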

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

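The tests with the Xist division as a block, with or without wild-type replicate 3, were chosen after the results were seen. The immediate early and stress list kept its call and direction under all 17 alternatives (camera adjusted p from 2.37e-24 to 1.04e-06), and the lists of late B, plasma cell, T cell, conventional dendritic cell, basophil and stem cell genes passed under none. No gene and no probe set passed under the alternatives other than those named here. Array weights gave 8452 genes (3483 higher, 4969 lower) and 19934 probe sets (9308 higher, 10626 lower), Hdac7 at 0.48 (adjusted p = 0.0347), early B genes at 0.708 and erythroid genes at 0.0346. The weights ran from 0.0716 for wild-type replicate 3 to 8.68 for wild-type replicate 1, with 4.12 for HDAC7-deficient replicate 2, so that this fit rests on few arrays. limma's default estimator of the weights stopped before convergence and its gene-by-gene estimator was used. The replicate number as a block gave 1 gene (1 higher), Hspa1b with 0.0415, and cell cycle genes at 0.0411, and moved no other call. Deviations of same-numbered arrays correlated at 0.0964, 0.208 and 0.476 across genes, the last being the highest of all pairs. The other pairs ran from -0.578 to 0.357, the latter for HDAC7-deficient replicate 1 with wild-type replicate 2. A link between same-numbered arrays is thus neither shown nor excluded. Repeated quantile normalization gave early B genes 0.591 and deacetylase genes 0.0697, and median centring, which shifts every change by 0.14, gave early B genes 0.0705. Without the dimmest 25% of genes, early B genes had 0.260 and interleukin 7 genes 0.0783. Without the dimmest 50%, early B genes turned downward at 0.762, natural killer genes had 0.301, neutrophil genes 0.114, cell death genes 0.109, interleukin 7 genes 0.552, interferon genes 0.0770 and deacetylase genes 0.186; fewer genes were then compared. The Xist block gave V(D)J genes 0.00279, cell cycle genes 0.00125 and stromal genes 0.0422 (downward), each with adjusted p = 0.453 with an estimated correlation. The Xist block without wild-type replicate 3 gave 4 genes (4 higher), 2 probe sets (2 higher), V(D)J genes 5.09e-04, natural killer and macrophage genes 0.129 each, plasmacytoid genes 0.128, neutrophil genes 0.839 (turned downward), interleukin 7 genes 0.298, interferon genes 0.839, cytokine genes 0.0660, sex-linked genes 0.0269 and stromal genes 0.0269 (downward), those that pass having adjusted p = 0.943 with an estimated correlation. This fit compares HDAC7-deficient replicate 1 with wild-type replicates 1 and 2 and assumes that the lone array varies like the others. With each array left out in turn, early B genes ran from 0.00273 (without wild-type replicate 2) to 0.920 (without wild-type replicate 3, turned downward), with 0.488 without HDAC7-deficient replicate 1. V(D)J genes ran from 0.0252 (without wild-type replicate 2) to 0.904 and passed also without HDAC7-deficient replicates 2 (0.0367) and 3 (0.0345). Erythroid genes ran from 9.52e-04 (without HDAC7-deficient replicate 1) to 0.930 and passed also without wild-type replicate 3 (0.0413). Cell cycle genes ran from 0.00343 (without wild-type replicate 2) to 0.535, passed upward without wild-type replicate 1 (0.0217) and HDAC7-deficient replicates 2 (0.0174) and 3 (0.0263), and turned downward without wild-type replicate 3 (0.0429). Deacetylase genes ran from 7.75e-04 to 0.0678 (without wild-type replicate 3). Where no reason is given, the cause was not tested. Of 145 named genes at most 3 changed sign in any setting, except 13 with the Xist block and wild-type replicate 3 left out. Pseudocounts do not apply to log2 values, and the robust variance model was not run for lists because camera does not use it. Signal over background limits what can be read from dim genes; the antigenomic controls had medians of 3.70 to 3.99 and the 25th percentiles of the arrays were 4.72 to 5.29.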

Other observations

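The tests of wild-type replicate 3, of the Xist division, of background, of genomic DNA and of Ssty1 and Ssty2 were chosen after the result was seen. So were the conditions on spread and number of arrays in the Xist test, and the reading of wild-type replicate 2 in the genomic DNA test. The same holds for the requirement that lineage lists also pass with the Xist block and without wild-type replicate 3. The genes named in the next paragraph, and the most abundant lineage genes named further below, were likewise chosen after their values were seen. Of those most abundant lineage genes, Tfrc and Car2 alone also follow the naming rule.

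Transcripts of neutrophils and their precursors were abundant on the arrays of both groups, although the gate selects B220+ cells. Mpo, the peroxidase of early granules, was 11.20 ± 1.12 in wild type and 11.70 ± 0.11 in HDAC7 deficient, and S100a9, a calcium-binding protein of neutrophils, was 11.38 ± 0.45 and 11.37 ± 0.29 (SD, n = 3 each). Without wild-type replicate 3 the early granule genes Elane, Prtn3, Ctsg and Ms4a3 had changes of -0.30, -0.51, -0.42 and -0.42, and the late granule genes Ltf, Camp and Lcn2 had changes of 0.32, 0.62 and 0.58. Within the Xist-low arrays these late granule genes had -0.25, 0.06 and -0.01, so that their positive changes come from the Xist-high arrays of HDAC7-deficient replicates 2 and 3 against Xist-low wild-type arrays. This does not hold for every neutrophil gene. The protease genes Mmp8 and Mmp9 had 0.59 and 0.38 within the Xist-low arrays, where the median of the neutrophil list was -0.04. The difference between early and late granule genes was not tested.

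Immediate early genes and 1 of 3 probe sets of the heat shock gene Hspa1b were higher on the arrays labelled HDAC7 deficient. The poor quality of wild-type replicate 3 is argued against as the whole cause, since the list still passed camera without it (2.93e-23, where all alternatives ran from 2.37e-24 to 1.04e-06, but adjusted p = 0.715 with an estimated correlation). The Xist division may contribute and stays open, since the list had a median of 0.664 within the Xist-low arrays and passed with the block (1.39e-07, but adjusted p = 0.453 with an estimated correlation), yet within those arrays this rests on HDAC7-deficient replicate 1 alone, which lay above both wild-type arrays in 19 of 25 members, by medians of 0.736 and 0.641 where those wild-type arrays differed from each other by 0.225. A stress of handling or sorting that differed between the groups may account for the pattern and cannot be told apart from genotype. The 10 measured heat shock genes, of which Hsp90aa1 and Dnajb1 are also in the list, had a median change of 0.395 with all 6 arrays. This lay above the 0.25 set as the bound, but several of them are strongly expressed, and wild-type replicate 3 read such genes lower. The 4275 genes of highest mean expression had 0.56 in the same fit, so 0.395 does not speak for a stress. Without wild-type replicate 3 the heat shock genes had 0.160, below the bound, which leaves a stress without a heat shock response open. The median standard error of the single genes was 0.156, which is not the error of their median. A response to the loss of HDAC7 stays open and untested.

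Genes of innate lineages were higher on the arrays labelled HDAC7 deficient. Cells of another type within the gate may contribute, and 5 lists passed upward without wild-type replicate 3 (natural killer, macrophage, neutrophil, plasmacytoid and erythroid genes, each with adjusted p = 0.715 or 0.725 with an estimated correlation), but 0 of them passed with that array left out and the Xist block as well, where 4 passed with the block alone (adjusted p = 0.453 with an estimated correlation), so that other cells, the Xist division and genotype cannot be told apart. Plasmacytoid dendritic cells carry B220 and would not be removed by this part of the gate, while neutrophils, macrophages and erythroid cells in general lack it. Of 20 plasmacytoid genes 4 are also in another list and 16 lay above the median gene on all wild-type arrays, and the most abundant, Irf8, Cox6a2 and Lair1, had changes of 0.07, 0.31 and 0.15 without that array. These counts were 8 and 18 of 27 for macrophages and 3 and 12 of 22 for natural killer cells. They were 0 and 16 of 19 for neutrophils and 0 and 4 of 18 for erythroid cells. Without that array the most abundant macrophage genes, Mpeg1, Lyz2 and Itgb2, had changes of 0.10, 0.26 and 0.11. Those of natural killer cells, Nkg7, Klrd1 and Gzma, had -0.18, 0.27 and -0.11. For neutrophils Mpo, S100a9 and S100a8 had -0.14, 0.24 and 0.25, and for erythroid cells Tfrc, Hba-a1 and Car2 had 0.33, -0.02 and 0.76. Derepression after loss of HDAC7 stays open and untested.

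Genes lower on the arrays labelled HDAC7 deficient were mostly weakly expressed. Of the 157 genes picked as silent in blood cells 17.2% lay below all wild-type arrays on all of these arrays, against 16.8% of all genes. A general rise of background on wild-type replicate 3 is argued against, since its antigenomic controls had a median of 3.70 where the other arrays had at least 3.75, but this array accounts for much of the median shift of dim genes, which went from -0.30 in the 4274 dimmest and -0.38 in the next 4274 to -0.11 and -0.18 without it, and why it read them higher stays open. Genomic DNA carried into the amplification is a candidate explanation that stays open for wild-type replicates 1 and 3. Their medians of the genes picked as silent lay at least 0.318 above those of every array labelled HDAC7 deficient. But wild-type replicate 2, at 5.08, lay below HDAC7-deficient replicate 3 at 5.25. The picked set can hold expressed genes, so its median need not be that of silent genes alone. The multicopy Y-linked testis genes Ssty1 and Ssty2, a possible mark of male DNA, were 4.43 and 4.85 higher on wild-type replicate 1 than on HDAC7-deficient replicate 1, with wild-type replicate 2 between them at 7.40 and 7.39. An effect of genotype on weakly expressed genes stays open and untested.

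The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. No gene passed in the real split or in any other, and probe sets gave 0 in the real split and at most 1 in the others. With a real count of 0, all 10 of 10 splits give at least as many by construction, so these counts say nothing about chance. The 1 probe set came from the split that follows Xist. For lists 7 of 10 splits gave as many as the real 11, and the highest other gave 15. The immediate early list had an adjusted p of 7.13e-13 in the real split, 9.60e-12 with wild-type replicate 1 and HDAC7-deficient replicates 2 and 3 against the rest, and 2.53e-11 in the split that follows Xist. At an unadjusted p under 0.05 the real split gave 2165 genes and the highest other 2462, with wild-type replicates 1 and 3 and HDAC7-deficient replicate 3 against the rest.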
